A study of Homo sapiens with 54 samples.

How the data were processed

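RNA from 6 established human cancer cell lines, treated with a kinase inhibitor or left as controls, was sequenced from the 3′ ends of transcripts with the Lexogen QuantSeq kit from 500 ng of RNA, per the labels. Per the processing notes, the authors trimmed reads with Trimmomatic, aligned them with STAR to the human genome build hg38 and counted them per gene with featureCounts; versions, annotation and filters are not stated. The 2 deposited tables hold raw counts per gene and library, whole numbers with no normalisation, checked on the values. Both name the same 33119 genes by symbol. The symbols were used as given; 23418 of them occur in the RefSeq gene table of GRCh38, which served only for positions, and 26 symbols had been turned into dates. The table of the first set also holds 5 lines of reads given to no gene, which were kept out of every fit. The second table repeats the 12 libraries of the first with identical values, and these copies were not used again. 3′ counts follow transcript ends, so they are not corrected for gene length.

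The 54 libraries were grouped as the labels state into 18 groups of 3 by line, drug and table. No label gives a dose, an exposure time, a date of culture or a pairing of libraries. Set 1 and set 2 were analysed apart and never pooled. The 17 comparisons were 10 of a drug with its own line's controls, 5 of a drug effect between lines that received the same drug in the same set, and 2 of trametinib with palbociclib. The comparisons, the gene lists, the rule for naming genes and most alternatives were set before the data were examined.

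Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each comparison was fitted on its own groups: genes were kept by filterByExpr (a minimum count of 10 and a minimum total of 15), libraries were scaled by TMM, and a quasi-likelihood model with a mean per group was tested two-sided. A difference between lines was tested as the difference of the drug effects. P-values were adjusted by Benjamini and Hochberg over the genes tested in a comparison, with a threshold of 0.05. Fold changes are log2 values from the fit, drug minus control unless stated, with standard errors derived from the test statistic. Levels are CPM, the counts of a gene scaled to a common library total with TMM, with the SD over 3 libraries. Levels by line and reads of other lines are CPM of the library total without TMM.

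Gene lists, 30 in number, were tested with camera of limma 3.58.1 against all other tested genes, with a preset correlation between genes of 0.01, where at least 5 members were tested, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. Beside each list the number of members past the threshold is given over all genes and adjusted over the list alone. A list score is the mean log2 CPM of the tested members, with a prior count of 2, minus the mean of the line's controls. The genes named for a drug comparison are the 8 highest and 8 lowest fold changes among called genes with a mean log2 CPM of at least 4 whose treated libraries all lie on 1 side of all controls, up to 4 called members of each list described, and a fixed set of targets for each drug. For differences between lines and between drugs they are the 5 highest and 5 lowest. Some genes that meet the rule are left out for length, and symbols that are only clone or locus identifiers are not named.

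Alternatives were size factors of DESeq2, no filter on low counts, DESeq2 1.42.0 in place of edgeR, all groups of a set in 1 fit, the replicate number as a block, an absolute log2 fold change of at least 1, each library left out in turn, and, chosen after seeing the data, a robust estimate of the dispersion. Fits were tested on simulated data with 200 changed genes at the depth and spread of each comparison. Genes were drawn independently, at the spread fitted for their level, so libraries that depart as a whole from their group were not simulated. Reads of genes that mark another line were summed as a percent of that line's own control level, over genes of at least 100 CPM there and under 1 CPM in the controls of the library's own line in set 2. The sums in set 2 controls are therefore low by choice. A higher sum with a drug in set 2 does not by itself show RNA of another line. Depth per library ranged from 3401565 to 12806042 counts. PCR copies cannot be told from separate molecules, so a floor of 3 counts covers counting error only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.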

Results

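RNA was measured by 3′ end sequencing in 6 established human cancer cell lines, each grown with a kinase inhibitor or without it. SW48 and SW620 are colorectal lines, NCI-N87 and MKN-45 are stomach lines, and BT-20 and BT-474 are breast lines. The colorectal lines received trametinib, an inhibitor of the kinases MEK1 and MEK2, or palbociclib, an inhibitor of the cell-cycle kinases CDK4 and CDK6, while the stomach and breast lines received afatinib, an irreversible inhibitor of the ERBB receptor family. The 54 libraries form 18 groups of 3 and come in 2 sets. Set 1 holds 12 libraries (SW48 and SW620, control and trametinib) with 4063382 to 10622670 counts each, and set 2 holds 42 libraries (the colorectal lines with control, trametinib or palbociclib, and the other 4 lines with control or afatinib) with 3401565 to 12806042 counts. The shallowest groups were NCI-N87 with afatinib (3401565 to 5675326 counts) and SW48 with trametinib in set 1 (4063382 to 5211206 counts). Doses and exposure times are not given in the sources used here. Nothing states that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

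In untreated cells ERBB2 (chromosome 17, 39688094 to 39728658), the receptor HER2, stood at 2054 ± 367 CPM (counts scaled to a common library total; SD, n = 3) in NCI-N87 and 1042 ± 22.6 CPM in BT-474, against 126 ± 8.67 CPM in BT-20 and 83.8 ± 4.51 CPM in MKN-45. EGFR, the epidermal growth factor receptor, was highest in BT-20 at 492 ± 23.6 CPM among the set 2 controls, and MET, the hepatocyte growth factor receptor, in MKN-45 at 1167 ± 56.3 CPM. CDX2, an intestinal transcription factor, stood at 98.4 ± 7.71 CPM in SW48 of set 2, and VIM, the mesenchymal filament vimentin, at 204 ± 2.85 CPM in SW620. In SW48 the ERBB2 level was 942 ± 43.9 CPM in the set 1 controls and 102 ± 7.55 CPM in the set 2 controls, although the control means of the line correlated at 0.981 across genes between sets (0.987 for SW620; genes are not independent replicates). In SW620 GATA3, a luminal transcription factor, stood at 77.6 ± 17.2 CPM in set 1 and 5.52 ± 0.691 CPM in set 2, and CDX2 at 2.77 ± 0.920 and 30.1 ± 1.43 CPM. These levels between lines and sets were not tested. Over all 17 comparisons, camera with its preset correlation placed a list apart from other genes 180 times, and with an estimated correlation 46 times.

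**Figure D1:**
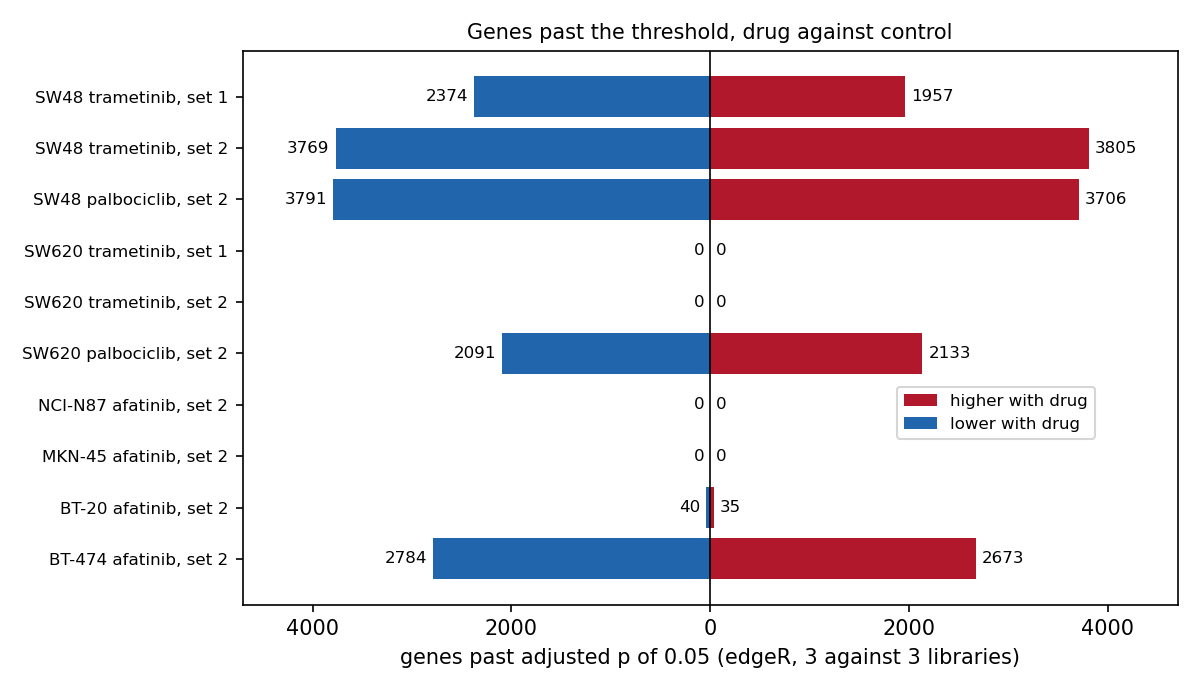
Number of genes past an adjusted p of 0.05 in each drug comparison (edgeR, 3 treated against 3 control libraries); bars to the right count genes higher with the drug and bars to the left genes lower with it. The bars range from 0 genes in both SW620 trametinib comparisons, NCI-N87 and MKN-45 to 7574 genes in SW48 with trametinib in set 2. The set 2 fits of SW48 and SW620 also held the other drug's libraries.

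In SW48 cells of set 1, trametinib lowered most tested genes of MEK/ERK output and all tested genes of ATF4 and amino acid synthesis. DUSP6 (chromosome 12, 89347235 to 89352501), a phosphatase that feeds back on ERK, fell from 170 ± 3.31 to 13.5 ± 2.25 CPM (log2 fold change −3.65, SE 0.14, adjusted p = 2.9e-06). FOSL1, a subunit of the transcription factor AP-1, fell by 4.11 on the log2 scale, ETV5, an ETS transcription factor, by 2.98, CCND1, which encodes cyclin D1, by 2.17 and MYC by 1.64. SPRY4, an inhibitor of receptor signalling, (−0.19, adjusted p = 0.85) and ETV4 (−0.51, adjusted p = 0.23) did not pass the test. Of 20 tested genes of MEK/ERK output 15 fell and 1 rose, with the same counts adjusted over the list alone. All 20 tested genes of the ATF4 and amino acid synthesis list fell, also adjusted over the list alone, with a median of −3.41. Among them ASNS (chromosome 7, 97851677 to 97928441), the asparagine synthetase, went from 386 ± 34.7 to 18.7 ± 1.71 CPM. CHAC1, which degrades glutathione, fell by 5.04, DDIT4, a brake on the growth kinase complex mTORC1, by 4.50, DDIT3, the stress factor CHOP, by 4.26 and TRIB3, a pseudokinase induced by ATF4, by 4.23. STEAP2, a metalloreductase, and TSC22D3, a glucocorticoid-induced leucine zipper protein, fell by 4.80 and 4.62. Both lists passed the camera test with a preset correlation (adjusted p = 5.3e-22 and 8.7e-65) and with an estimated correlation (adjusted p = 0.018 and 0.023).

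Within the limits for named genes, those that rose most in that comparison were IQGAP2, a cytoskeletal scaffold (4.84, SE 0.47), TUBA1A, an alpha-tubulin (4.19, SE 0.62), and AXIN2. AXIN2 (chromosome 17, 65528563 to 65561648), a WNT target and inhibitor, went from 82.0 ± 40.5 to 1294 ± 183 CPM. HOXB5, a homeobox factor, rose by 3.62 and IFI6, an interferon-induced gene, by 3.28. Of 28 tested genes of G2/M and mitosis 23 rose (24 adjusted over the list alone), MKI67, the proliferation marker Ki-67, from 62.2 ± 16.3 to 496 ± 62.7 CPM and CENPE, a kinetochore motor, by 2.67, with adjusted p = 0.060 with an estimated correlation. Of 20 interferon-stimulated genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.097 with an estimated correlation). Among 12 WNT targets and stem cell genes 5 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.097 with an estimated correlation), NOTUM, an enzyme that inactivates WNT ligands, by 8.36 from 0.197 ± 0.0799 CPM. Of 24 cytosolic ribosomal protein genes 22 fell (23 adjusted over the list alone), with a median of −0.64 and adjusted p = 0.11 with an estimated correlation. Of 7 mesenchymal genes 4 rose, also adjusted over the list alone, among them COL1A1, a collagen, by 3.72 (adjusted p = 0.097 with an estimated correlation). Beside these genes, reads of genes that mark the other lines summed to up to 22.6% of those lines' own level in the trametinib libraries. That was for MKN-45 genes in trametinib 2 (4.30% without PPP1R1B). In the controls the sums reached 12.1%, for BT-20 genes in control 1 (8.25% without the highest gene). A median gene stood at up to 1.34% with trametinib and 1.78% in the controls. The genes were chosen against SW48 controls of set 2, so differences between the sets add to these sums. Some genes, however, stood at 50 CPM or more in 1 library with no count in the others of its group. They numbered 3, 1 and 1 in controls 1, 2 and 3, and 2, 1 and 0 in trametinib 1, 2 and 3. The highest was UPK1B at 301 CPM in trametinib 1. Such genes are not a difference between the sets, and their source was not tested. The mitochondrial ribosomal RNAs RNR1 and RNR2 made up 4.64 to 5.64% of counts in the trametinib libraries and 1.63 to 3.81% in the controls, and a mean of 44.7% and 29.0% of reads were not aligned. In all, 1957 genes were higher and 2374 lower among 12235 tested, 823 and 1027 of them by at least 2-fold, and DESeq2 called 4426. The count was 2227 with all 4 groups of the set in 1 fit. IGFBP5, a binding protein of insulin-like growth factors, had the lowest fold change within the limits for named genes (−6.15, SE 1.84). It stood at 480 ± 775 CPM in controls. Its call was lost without control 1 (−2.21) or without any 1 trametinib library (−8.40 to −5.56), and also with a robust dispersion.

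In SW48 cells of set 2, AREG and EREG, ligands of the EGF receptor, were among the genes that fell most with trametinib, by 4.63 and 4.24 on the log2 scale. KRT16, a stress keratin, fell by 6.26 (SE 0.15), CHAC1 by 5.55, DDIT4 by 5.23, DDIT3 by 4.43 and GDF15, a stress-induced cytokine, by 4.41. DUSP6 fell from 378 ± 19.5 to 67.2 ± 4.29 CPM (−2.49, SE 0.07, adjusted p = 5.5e-14), and all the other MEK targets set for this drug fell too, SPRY4 by 1.83, ETV4 by 2.31, ETV5 by 2.53, CCND1 by 1.86, FOSL1 by 3.09 and MYC by 1.99. Within the limits for named genes TMEM54, a membrane protein, rose most (2.64, SE 0.08). YPEL3 rose by 2.56, IFI6 by 2.44, PLIN3, a lipid droplet coat protein, by 2.39, SEMA3C, a secreted guidance factor, by 2.37 and C1R, a complement protease, by 2.31. All 20 ATF4 and amino acid genes fell, with a median of −2.91, and of 20 MEK/ERK output genes 18 fell and 1 rose, with a median of −2.40. Of 22 ribosome biogenesis genes 21 fell, led by PNO1 at −1.59. Of 24 cholesterol synthesis genes 20 rose and 1 fell, INSIG1, a sterol sensor, by 1.69. Among 28 G2/M genes 19 rose, KIF20A, a mitotic kinesin, by 1.07 and MKI67 by 0.79, and of 18 interferon-stimulated genes 12 rose and 1 fell. Each of these counts was the same adjusted over the list alone, and each list passed with an estimated correlation (adjusted p = 0.00074, 0.0020, 0.0020, 0.022, 0.023 and 0.019 in that order). Of 12 MHC class I genes 9 rose and 1 fell, also adjusted over the list alone, with adjusted p = 0.052 with an estimated correlation. Reads of genes that mark the other lines summed to up to 4.23% of those lines' own level in the trametinib libraries, for BT-20 genes in trametinib 3 (0.311% without STC1). Genes that mark MKN-45 summed to 0.588% in that library. The sums were up to 0.198% in the controls, where these genes were chosen to be low. A median gene stood at up to 0.155% with trametinib and 0.128% in the controls. RNR1 and RNR2 made up 2.25 to 3.33% of counts with trametinib and 0.970 to 1.60% in the controls. Of 13076 genes tested 3805 were higher and 3769 lower, 1095 and 875 by at least 2-fold, and DESeq2 called 7086.

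The SW48 sets shared 1405 genes higher and 1700 lower with trametinib, where independent lists of those lengths would share 580.3 and 713.4 of the 12054 genes tested in both. Opposite calls numbered 201, against 1293 for independent lists. Fold changes correlated across genes at r = 0.654 (Spearman 0.639); genes are not independent replicates. AXIN2, NOTUM and CDX2 rose in both sets; NOTUM rose by 1.46 in set 2, where controls already held 228 ± 7.97 CPM, and CDX2 by 2.27 in set 1 and 1.40 in set 2.

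In SW620 cells trametinib gave no gene past the threshold in either set. In set 2 MYC stood at 82.8 CPM with trametinib and 151 CPM in controls (−0.87, SE 0.18, adjusted p = 0.090), AREG at −1.61 (adjusted p = 0.11), EMP1, a membrane protein of the MEK/ERK list, at −1.27 (adjusted p = 0.095) and DUSP6 at −0.28 (adjusted p = 0.43). Camera nevertheless placed 12 lists apart from other genes, none of them with an estimated correlation (adjusted p from 0.35 to 0.38). The G2/M list had a median of 0.27, cholesterol synthesis 0.40, WNT targets 0.39, MEK/ERK output −0.28, and ATF4 and amino acid synthesis −0.48. Adjusted over the list alone, 12 of 28 G2/M genes, 11 of 23 cholesterol genes and 10 of 17 WNT targets were higher, 3 of 20 MEK/ERK genes were lower and none of 22 ATF4 genes passed. edgeR called 0 of 13484 genes in set 2 (2492 at an unadjusted p under 0.05, and 501 by DESeq2). In set 1 edgeR called 0 of 13081 genes and DESeq2 called 14. At an unadjusted p under 0.05 there were 366 genes in set 1, and 1124 at that unadjusted threshold without control 3. The 366 lie below the share of 0.05 of tested genes that unchanged genes give on average. Simulated 2-fold changes were recovered for 79% of genes at the depth and spread of set 2 but for 9% in set 1. Simulated genes varied independently, so these shares do not cover libraries that differ as a whole, and the 0 calls do not show absence of an effect. The 3 trametinib libraries of set 2 had ATF4 and amino acid synthesis scores of 0.00, −0.36 and −1.76; without trametinib 1 the count was 1347, with 6 of 22 ATF4 genes, 11 of 22 ribosome biogenesis genes and 7 of 20 MEK/ERK genes lower and 13 of 23 cholesterol genes and 10 of 17 WNT targets higher. MYC (−1.10), AREG (−2.39) and EMP1 (−1.84) then passed, as they did with DESeq2 (−0.88, −1.64 and −1.29), and COL9A3, a collagen, at 2.35 and SFRP5, a WNT antagonist, at 2.07 were among the highest. Trametinib 1 lay nearest to the controls on the ATF4 and amino acid synthesis score. Leaving it out therefore favours calls, and the values without it are no independent support for a response. Without control 3 of set 2 the count was 2, the filter on low counts left off gave 864, and all set 2 groups in 1 fit gave 632. In set 1, camera placed immediate early genes (median −0.49), ERBB receptors and ligands (−0.42) and MHC class I genes (−0.51) lower, with adjusted p = 0.52, 0.52 and 0.75 with an estimated correlation and no member called on either adjustment. All 3 calls ended without control 1 (−0.46, −0.52 and −0.50), control 3 (−0.21, −0.44 and −0.35) or trametinib 3 (−0.54, −0.41 and −0.54), and that of the ERBB list also without control 2 (−0.42) or trametinib 2 (−0.40). Without control 3 camera instead placed cholesterol synthesis (−0.20) and glycolysis genes (−0.20) lower, with no member called. Genes that mark BT-474 summed to 10.9, 1.40 and 11.3% of their BT-474 level in the set 1 controls, with PGR at 1041, 2 and 1787 counts and a median gene at 1.78, 1.40 and 1.20%. With trametinib they summed to 0.598 to 0.730%, with a median gene at 0.0401 to 0.310%. Genes that mark MKN-45 summed to 9.59% in control 3 (0.666% without AGR2) and to 0.400 to 1.34% with trametinib. All set 1 groups in 1 fit called 2 genes. Fold changes of the sets correlated at r = −0.0194 across genes.

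The trametinib effect was tested for a difference between the lines. In set 2, the change was higher in SW620 than in SW48 for CHAC1 by 5.28 (SE 0.65), DDIT4 by 4.54, PHLDA1, a stress-induced gene of the MEK/ERK list, by 3.96 (SE 0.13) and ERRFI1, an inhibitor of EGF receptor signalling, by 3.88, and lower for IFITM2, an interferon-induced membrane protein, by 3.04 and TMEM54 by 2.76. Of 20 MEK/ERK genes 17 had a higher and 1 a lower change in SW620, also adjusted over the list alone (adjusted p = 0.029 with an estimated correlation). Of 22 ATF4 and amino acid genes 18 had a higher change (19 adjusted over the list alone), with adjusted p = 0.18 with an estimated correlation. In set 1, ATF4 and amino acid genes differed in 19 of 22 (20 adjusted over the list alone; adjusted p = 7.7e-05 with an estimated correlation) and MEK/ERK genes in 10 of 20 (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.00017 with an estimated correlation). The counts were 2146 higher and 1813 lower of 14027 genes in set 2, and 574 higher and 404 lower of 14525 in set 1. EIF3C, at 8.20 in set 1, has the near-identical copy EIF3CL and its value is uncertain, and GSTP1 (−5.04) lost its call without any 1 library except SW620 control 1, 2 or 3 (−5.22 to −4.77). The set 1 count was 1821 by DESeq2 and 2439 without SW620 control 3; without any 1 other library except SW620 control 1 or 2 it was 493 to 619.

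**Figure D2:**
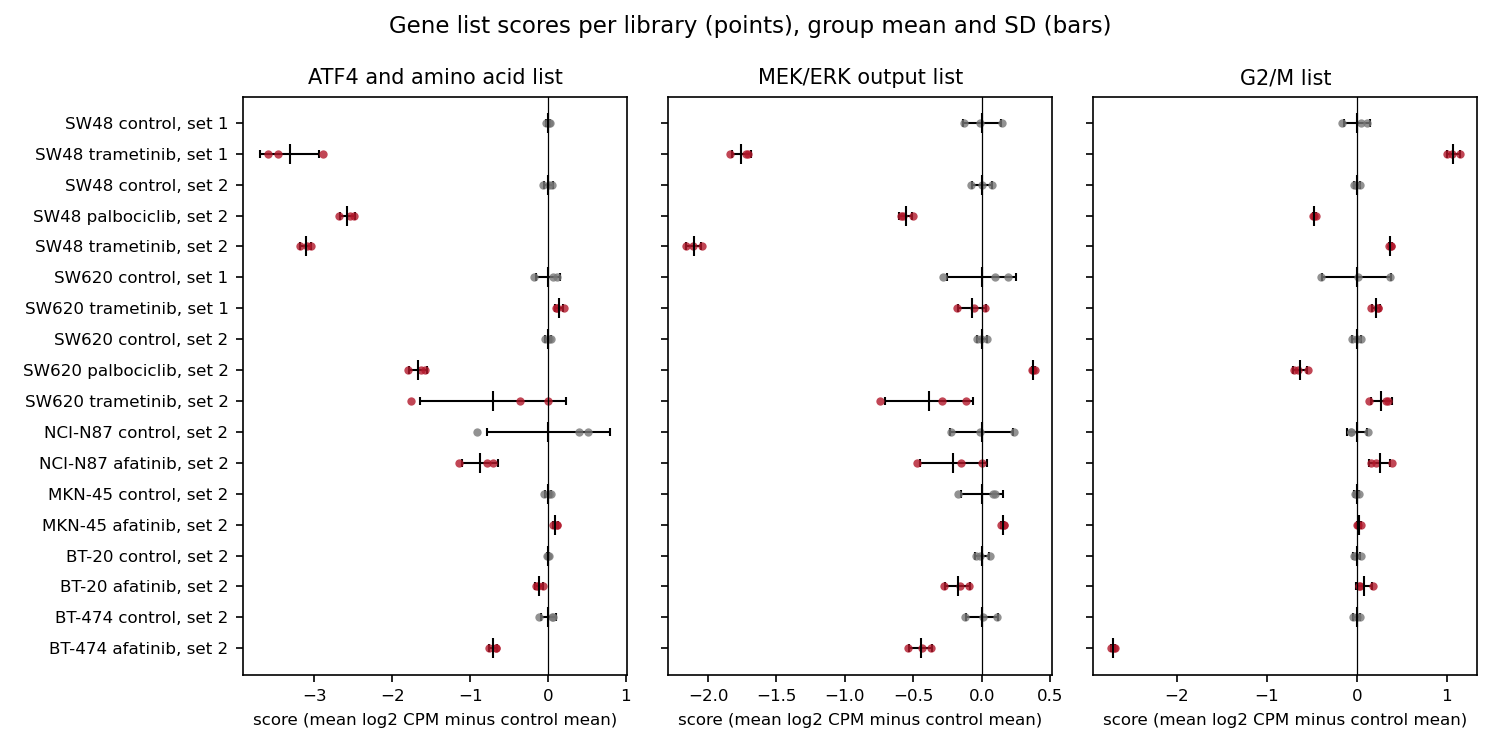
Scores of the ATF4 and amino acid, MEK/ERK output and G2/M lists in each library (mean log2 CPM of the tested members minus the mean of the same line's controls in the set); points are libraries, bars the group mean and SD, grey points controls and red points drug-treated libraries. The SW620 trametinib libraries of set 2 spread from 0.00 to −1.76 on the ATF4 and amino acid synthesis list.

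Palbociclib lowered the amino acid stress genes and the DNA replication genes of SW48. DDIT4 fell from 898 ± 40.2 to 37.6 ± 5.17 CPM (−4.57, SE 0.10, adjusted p = 2.5e-14), CHAC1 by 4.24, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, by 3.63, ASNS by 3.50 and DDIT3 by 3.24. CRIP2, a LIM domain protein, rose by 2.61, MXD4, which opposes MYC, by 2.47, ID3, an inhibitor of differentiation factors, by 2.45, SESN3, a stress-induced sestrin, by 2.33 and SMPD1, the acid sphingomyelinase, by 2.25. MCM2, a replication helicase subunit, fell by 0.58, E2F1 by 0.52, MKI67 by 0.37, CCNB1, cyclin B1, by 0.29 and CCND1 by 0.30, while CDKN1A, the inhibitor p21, rose by 0.62 and CCNE2, a cyclin E, did not pass (−0.23, adjusted p = 0.16). All 20 ATF4 and amino acid genes fell. Of 29 G1/S and DNA replication genes 24 fell and 2 rose, CDC6, a replication licensing factor, by 1.10 and MCM10 by 0.97, and of 28 G2/M genes 22 fell, AURKB, a mitotic kinase, by 0.99. Of 22 ribosome biogenesis genes 19 fell and 1 rose, of 24 cholesterol genes 16 rose, and of 18 interferon-stimulated genes 10 rose. Adjusted over the list alone these counts were the same, and all 6 lists passed with an estimated correlation (adjusted p from 0.0010 to 0.045). Of 20 MEK/ERK genes 13 fell and 4 rose (14 and 4 adjusted over the list alone), FOSL1 by 2.01, with adjusted p = 0.12 with an estimated correlation. Of 11 intestinal differentiation genes 9 rose (9 adjusted over the list alone), MUC13, a mucin, by 2.72, with adjusted p = 0.13 with an estimated correlation. In all, 3706 genes were higher and 3791 lower of 13076, 969 and 659 by at least 2-fold, and DESeq2 called 7022. Genes of the other lines summed to up to 4.09% of those lines' level in these libraries, for BT-20 genes in palbociclib 1 (0.329% without STC1). Genes that mark MKN-45 summed to 0.559% in that library. The sums were up to 0.198% in the controls, where these genes were chosen to be low. A median gene stood at up to 0.153% with palbociclib and 0.128% in the controls. RNR1 and RNR2 made up 2.93 to 4.52% of counts with palbociclib and 0.970 to 1.60% in the controls.

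In SW620 cells with palbociclib CCND2, cyclin D2, rose from 8.84 ± 0.792 to 56.1 ± 3.89 CPM (2.67, SE 0.13, adjusted p = 4.0e-07) and CCND1 (chromosome 11, 69641156 to 69654474) from 274 ± 7.79 to 815 ± 8.23 CPM (1.57, SE 0.12). MUC1, a membrane mucin, rose by 2.63, NGFR, the low-affinity neurotrophin receptor, by 2.52, FOLR1, a folate receptor, by 2.40 and SERPINA1, alpha-1 antitrypsin, by 2.15. INHBE, an inhibin subunit induced by stress, fell by 3.31, ASNS by 3.01, G0S2, an inhibitor of fat breakdown, by 2.46, PHGDH, the first enzyme of serine synthesis, by 2.43, TRIB3 by 2.42 and RBM3, a cold-induced RNA-binding protein, by 2.25. MKI67 fell by 0.66 and CCNB1 by 0.32, although CCNB1 lost its call without control 1 (−0.30), palbociclib 1 (−0.28) or palbociclib 2 (−0.32). E2F1 (−0.17, adjusted p = 0.38), MCM2 (−0.16, adjusted p = 0.22) and CCNE2 (0.04, adjusted p = 0.89) did not pass. CDKN1A was called at 4.26 (SE 0.91) but stood at 12.02 ± 14.6 CPM against 0.642 ± 0.36 CPM. Of 28 G2/M genes 25 fell (26 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation), HMMR, a spindle protein, by 1.07 and AURKB by 1.03. Of 29 G1/S genes 17 fell and 2 rose (19 and 2 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), CCNE1, a cyclin E, being among the 2 at 1.36. Of 22 ATF4 and amino acid genes 20 fell (21 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 23 (16 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation), and intestinal differentiation genes in 8 of 13 with 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), TFF3, a trefoil peptide, by 1.65. Lysosomal genes rose in 8 of 14 with 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation), CTSD, a lysosomal protease, by 1.22. In all, 2133 genes were higher and 2091 lower of 13484, 523 and 312 by at least 2-fold, and DESeq2 called 4296. Genes of the other lines summed to up to 4.48% of those lines' level, for BT-20 genes in palbociclib 3 (0.311% without STC1). Genes that mark SW48 summed to 1.22% in palbociclib 1 (0.591% without CDKN1A). The sums were up to 0.157% in the controls, where these genes were chosen to be low. A median gene stood at up to 0.353% with palbociclib and 0.206% in the controls.

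The palbociclib effect differed between the lines in 3626 of 14098 genes, 2052 with a higher change in SW620 and 1574 with a lower one. The change was higher in SW620 for EREG by 3.69 (SE 0.22) and PDGFB, a platelet-derived growth factor chain, by 2.83, and lower for HSPA1B, a heat shock protein, by 2.27 and FADS1, a fatty acid desaturase, by 2.15. CDKN1A (3.66) lost its call without SW620 control 3 (3.20) and with a robust dispersion. Of 20 MEK/ERK genes 13 had a higher and 1 a lower change in SW620, and of 22 ATF4 and amino acid genes 16 had a higher and 1 a lower one. Both counts were the same adjusted over the list alone (adjusted p = 0.0060 and 0.017 with an estimated correlation).

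Set directly against palbociclib, trametinib left cell-cycle genes higher and MEK targets lower in SW48. PHLDA1 was lower by 3.20 (SE 0.06), GDF15 by 3.01, CD55, a complement regulator, by 2.94, AREG by 2.88 and EMP1 by 2.77, and PRR15L was higher by 2.29 (SE 0.14). All 28 G2/M genes and 27 of 29 G1/S genes were higher and 18 of 20 MEK/ERK genes were lower, also adjusted over the list alone (adjusted p = 0.00074, 0.0011 and 0.0011 with an estimated correlation). In SW620 NGFR was lower with trametinib than with palbociclib by 3.05 (SE 0.24), CCND2 by 2.35 and B3GNT3, a glycosyltransferase, by 2.34, and ITPR2, a calcium channel, was higher by 2.80. All 28 G2/M genes were higher, also adjusted over the list alone (adjusted p = 0.086 with an estimated correlation), and 12 of 20 MEK/ERK genes were lower and 1 higher, also adjusted over the list alone (adjusted p = 0.25 with an estimated correlation). Direct calls numbered 2776 higher and 2689 lower in SW48, and 2203 higher and 2261 lower in SW620. Both drugs were compared with the same controls. In SW48 they shared 2433 genes higher and 2652 lower, against 1078 and 1093 for independent lists, with 364 opposite calls. Simulated unchanged groups against shared controls shared at most 1 call in all. Few genes can pass the test in unchanged groups. That value therefore cannot show how many of the observed shared calls come from the shared controls. Fold changes correlated at 0.716 across genes in SW48 and 0.266 in SW620, where unchanged groups against shared controls gave 0.496 and 0.504. The covariance was 0.495 in SW48 against a simulated 0.0201, and 0.0697 in SW620 against 0.0366. The 3 controls cannot be split into parts of at least 2 libraries, so part of the shared calls may come from the shared controls.

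Afatinib gave no gene past the threshold in either stomach line. In NCI-N87 CHAC1 stood at −2.23 (SE 0.52, adjusted p = 0.37), DDIT4 at −1.71, AREG at −1.57, EGFR at −0.71, DUSP6 at 0.01 and ERBB2 at −0.04, with 0 of 12472 genes called by edgeR, 1523 at an unadjusted p under 0.05 and 33 by DESeq2. Adjusted over the list alone, 17 of 20 ATF4 and amino acid genes were lower there, with a list median of −0.99 (camera adjusted p = 1.4e-14, adjusted p = 0.77 with an estimated correlation). Glycolysis genes had a median of −0.22 with 3 of 16 lower adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). The ATF4 and amino acid synthesis score was −0.91 in control 1, 0.39 and 0.52 in the other controls, and −0.70, −0.78 and −1.14 in the afatinib libraries. Without control 1 the count was 2108 (1053 higher, 1055 lower), with 18 of 20 ATF4 genes, 5 of 20 MEK/ERK genes and 4 of 8 ERBB receptors and ligands lower and 12 of 29 G1/S genes higher and 1 lower; CHAC1 stood at −2.68 (SE 0.16, adjusted p = 6.7e-05), S100P, a calcium-binding protein, at −2.55, DDIT4 at −2.10, AREG at −1.94 and EGFR at −0.89. Control 1 lay with the afatinib libraries on the ATF4 and amino acid synthesis score. Leaving it out therefore favours calls, and the values without it are no independent support for a response. The count was 2 without afatinib 3, 197 with no filter on low counts and 1427 with all set 2 groups in 1 fit. In MKN-45 edgeR called 0 of 12358 genes, with 664 at an unadjusted p under 0.05 and 0 by DESeq2, and DUSP6 stood at 0.19, EGFR at 0.18 and ERBB2 at 0.12. The 664 lie near the share of 0.05 of tested genes that unchanged genes give on average. Ribosome biogenesis genes had a median of −0.13 and immediate early genes of 0.16 there (adjusted p = 0.68 for both with an estimated correlation), with no member called on either adjustment. The camera call of both lists ended without MKN-45 control 2 (−0.0507 and 0.0499) or afatinib 1 (−0.13 and 0.21), and that of the immediate early genes also without afatinib 2 (0.11) or afatinib 3 (0.23). The count was 1 without MKN-45 control 1 or without control 2, and 7 with all set 2 groups in 1 fit. Simulated 2-fold changes were recovered for 70% of genes in NCI-N87 and 81% in MKN-45. No library that departs as a whole, such as NCI-N87 control 1, was simulated, so these shares do not turn 0 calls into absence of an effect.

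The afatinib effect differed between the stomach lines in 2 of 13791 genes, PMP22, a myelin membrane protein (4.26, SE 0.62), and FRAS1, a basement membrane protein (−4.97, SE 0.68), both at an adjusted p of 0.046 and both named after their values were seen, since their expression lies under the limit for named genes. Simulated 2-fold changes were recovered for 38% of genes in this difference between lines, so 2 calls do not show absence of other differences. Of 22 ATF4 and amino acid genes 16 had a lower change in NCI-N87 adjusted over the list alone and none over all genes (adjusted p = 0.41 with an estimated correlation). The count was 1315 without NCI-N87 control 1, with a lower change in NCI-N87 for 17 of 22 ATF4 genes. It was 4 without NCI-N87 afatinib 3, 1 without control 3 of either line, and 0 without NCI-N87 control 2 or afatinib 1, MKN-45 control 1 or 2, or any 1 MKN-45 afatinib library; DESeq2 called 23. FRAS1 passed only without NCI-N87 control 1, afatinib 2 or afatinib 3 and PMP22 only without NCI-N87 control 1 or afatinib 3; without any 1 other library they stood at −6.85 to −4.44 and at 3.95 to 4.41.

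In BT-20 afatinib changed 75 genes. Within the limits for named genes EGR1 (chromosome 5, 138465479 to 138469303), an immediate early transcription factor, fell most. It went from 148 ± 3.42 to 30.5 ± 4.50 CPM (−2.27, SE 0.10, adjusted p = 1.3e-07). KLK6, a secreted protease, fell by 0.72. HMOX1, heme oxygenase 1, rose from 44.3 ± 1.85 to 98.0 ± 21.6 CPM (1.14, SE 0.13) and ANGPTL4, an inhibitor of lipoprotein lipase, by 1.02. TXNIP, a thioredoxin inhibitor repressed by growth signals, rose by 0.76, PDK4, a brake on pyruvate oxidation, by 0.69 and HSPB8, a small heat shock protein, by 0.76, while FRMD4B, a scaffold protein, fell by 1.16 and ETV5 by 0.52. DUSP6 (−0.83, adjusted p = 0.14), EGFR (0.16, adjusted p = 0.47) and ERBB3 (0.22, adjusted p = 0.28) did not pass. Of 19 FOXO targets 2 rose (4 adjusted over the list alone), and of 20 MEK/ERK genes 1 fell (5 lower and 1 higher adjusted over the list alone), with adjusted p = 0.17 and 0.23 with an estimated correlation. Of 15 immediate early genes 2 fell (4 lower and 2 higher adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). PGR, the progesterone receptor, had no count in the controls and 3.96 ± 0.825 CPM with afatinib. Among 8 genes that mark BT-474, where PGR is high, the sum without PGR was 0.0216 to 0.0316% of their BT-474 level in the afatinib libraries. Of 12810 genes 35 were higher and 40 lower. The count was 6 without control 3, 7 without control 2, 22 without afatinib 2, 25 without control 1, 164 by DESeq2, 497 with no filter and 12 with all set 2 groups in 1 fit. With the replicate number as a block, a pairing that the libraries do not show, 5 genes remained, EGR1, KLK6, HMOX1, ANGPTL4 and HSPB8, while TXNIP (0.76, adjusted p = 0.052), PDK4 (0.69, adjusted p = 0.082), FRMD4B (−1.17, adjusted p = 0.082), ETV5 (−0.52, adjusted p = 0.079) and PGR (adjusted p = 0.055) lost their calls. EGR1, KLK6, HMOX1 and ANGPTL4 passed without any 1 library. TXNIP lost its call without control 2 (0.75) or control 3 (0.71), HSPB8 without control 2 (0.72), and PDK4 (0.64 to 0.70), FRMD4B (−1.12 to −1.05) and ETV5 (−0.54 to −0.48) without control 2, control 3 or afatinib 2.

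In BT-474 afatinib lowered nearly every tested gene of DNA replication and mitosis. FAM111B, a protease of replicating cells, fell by 5.14 (SE 0.14), PRR11, a cell-cycle gene, from 656 ± 12.95 to 31.2 ± 2.03 CPM (−4.40, SE 0.07, adjusted p = 1.9e-12), NUF2, a kinetochore protein, by 3.88, DUT, which hydrolyses dUTP, by 3.64, PTTG1, securin, by 3.62, PLK1, a mitotic kinase, by 3.53 and TPX2, a spindle factor, by 3.33. TXNIP (chromosome 1, 145992435 to 145996579) rose from 111 ± 51.7 to 1453 ± 82.2 CPM (3.71, SE 0.23), PCDH19, a protocadherin, by 2.81, TNFSF10, the death ligand TRAIL, by 2.78 and KLK10, a secreted protease, by 2.27. DUSP6 fell by 1.68, CCND1 by 0.36, and ERBB3 rose by 0.66, while ERBB2 (−0.08, adjusted p = 0.32), EGFR (−0.78, adjusted p = 0.096) and MYC (0.11, adjusted p = 0.31) did not pass. Without afatinib 3 ERBB2 (−0.16) and EGFR (−1.13) passed, as did EGFR without control 2 (−1.09). All 28 G2/M genes fell, with a median of −2.61, and 28 of 29 G1/S genes, with a median of −1.78, both the same adjusted over the list alone (adjusted p = 0.00088 for each with an estimated correlation). Of 19 FOXO targets 13 rose and 1 fell (14 and 2 adjusted over the list alone), FOXO1 by 1.38 and IGF1R, the insulin-like growth factor receptor, by 0.97, and of 22 ribosome biogenesis genes 18 fell, also adjusted over the list alone (adjusted p = 0.048 for both lists with an estimated correlation). Of 15 glycolysis genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), HK2, a hexokinase, by 1.79 and LDHA, a lactate dehydrogenase subunit, by 1.73. Of 20 ATF4 and amino acid genes 16 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.11 with an estimated correlation). Of 19 MEK/ERK genes 11 fell and 2 rose (11 and 3 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Of 12 luminal genes 7 rose and 3 fell, also adjusted over the list alone, PGR by 1.42 from 249 ± 4.20 CPM (adjusted p = 0.14 with an estimated correlation). Of 12 intestinal genes 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.14 with an estimated correlation), TFF2, a trefoil peptide, by 2.60. Genes that mark MKN-45 summed to 0.803 to 1.39% of their MKN-45 level in these libraries. They summed to 0.163 to 0.320% in the controls, where they were chosen to be low. In all, 2673 genes were higher and 2784 lower of 12768, 769 and 517 by at least 2-fold, and DESeq2 called 4340.

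The afatinib effect differed between the breast lines in 3336 of 14019 genes, 1429 with a higher change in BT-474 and 1907 with a lower one (1943 with all set 2 groups in 1 fit). The change was lower in BT-474 for PRR11 by 4.35 (SE 0.10), NUF2 by 3.94, HMMR by 3.92 and APOBEC3B, a cytidine deaminase, by 3.73, and higher for TXNIP by 2.93 (SE 0.30) and JAG1, a Notch ligand, by 1.93. All 28 G2/M genes and 28 of 29 G1/S genes (28 and 29 adjusted over the list alone) had a lower change in BT-474 (adjusted p = 4.9e-05 for both with an estimated correlation), as did 15 of 22 ATF4 and amino acid genes with 1 higher (16 and 1 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation).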

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

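The tests of depth in SW620 and of the drug effects between lines were chosen before their results were seen, and all the other tests given here, including the counts over other splits of the libraries, were chosen afterwards.

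The trametinib libraries of SW620 in set 2 differed among themselves in ASNS, CHAC1 and the other ATF4 and amino acid synthesis genes, with scores of 0.00, −0.36 and −1.76 against controls. After every library was thinned to the same depth the spread of the scores was 1.77, which argues against uneven depth, and genes that mark SW48 stood at a median of 0.0972% of their SW48 level, which argues against SW48 RNA in a library. The library with the lowest score had a G2/M score of 0.35 where the palbociclib libraries lay at −0.54 or lower, which argues against a palbociclib library under a trametinib label. Its MEK/ERK output score of −0.74, against −0.12 in the library with the highest ATF4 score, may reflect unequal MEK inhibition between cultures, but 3 libraries cannot decide that and the labels give no dose or time.

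Control 1 of NCI-N87 lay with the afatinib libraries in CHAC1, DDIT4 and AREG, and without it the count of genes changed by afatinib went from 0 by edgeR (1523 at an unadjusted p under 0.05, 33 by DESeq2) to 2108. An exchange of control 1 with an afatinib library would leave 1 afatinib library at the level of the other controls, but the highest ATF4 score among them was −0.70 where those controls stood at 0.39 or more. The share of the mitochondrial ribosomal RNAs was 8.15% in control 1, against 3.39 and 3.18% in controls 2 and 3. It was 10.3, 10.3 and 4.96% in the afatinib libraries, the last of them the library with the lowest score (−1.14). That library goes against the share as an explanation, but 1 library does not exclude it. Genes that mark SW620 summed to 0.147% of the SW620 level in control 1. The sums were 0.0904 and 0.107% in controls 2 and 3 and 0.264 to 0.501% with afatinib. These genes were chosen as under 1 CPM in every control, control 1 among them, so its low sum was set in advance. The reads also lie near the floor, so this comparison cannot decide and a wrong label for control 1 is left open. Exposure of that control to afatinib and a culture state shared with the afatinib libraries were not tested. No biological explanation was tested.

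Control 3 of SW620 in set 1 stood apart from controls 1 and 2, and a count was found for 15531 genes in it. Its profile correlated at 0.965 across genes with the SW620 controls of set 2, against 0.927 for the nearest other line, which argues against another line under an SW620 label. Genes that mark other lines reached a median of 1.20% of their level there and 1.78% in control 1, which argues against RNA of a whole other line as the reason. Summed, MKN-45 genes reached 9.59% in control 3 against 0.847 and 0.553% in controls 1 and 2, but AGR2 alone made up most of that (0.666% without it) and the median gene was 0 among 13. BT-474 genes summed to 11.3% against 10.9 and 1.40%, or to 3.69, 6.53 and 1.23% in controls 3, 1 and 2 without the highest gene of each. Thinned to the same total, control 3 had a count in 15450 genes and the next lowest control in 17846, which is consistent with fewer distinct RNA molecules in that library. A real change in expression predicts the same, and no biological explanation was tested.

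The effect of trametinib differed between SW620 and SW48 in 978 genes in set 1 and in 3959 in set 2, CHAC1 and DDIT4 among the highest in both. Among 50 splits of the libraries 6 gave as many genes in set 1, with 1210 as the highest of the others, and 3 in set 2, with 5324, so by that share chance was not excluded for either count. Every other split with as many calls kept the SW48 groups apart and so still held the drug effect in SW48, which is a structure of the samples and not chance. The palbociclib effect differed between these lines in 3626 genes, EREG and PDGFB among them, where 2 of 50 splits gave as many and the highest other, which also kept the SW48 groups apart, gave 3687. The afatinib effect differed between BT-474 and BT-20 in 3336 genes, PRR11 and TXNIP among them, where 1 of 50 splits, the real one, gave as many and the highest other, which kept the BT-474 groups apart, gave 3224. These 2 shares lie under 0.05, but the highest other splits there too held the drug effect of 1 line. Such a share depends on how many other splits kept a line apart, 10 for palbociclib and 5 for the breast lines. The shares alone therefore neither exclude chance nor decide between chance and structure in any of these comparisons. Between NCI-N87 and MKN-45 it differed in 2 genes, PMP22 and FRAS1, where 14 of 50 splits gave as many and the highest other gave 4, and chance was not excluded. With no line kept apart the highest count was 3 and 2 for trametinib in set 1 and set 2, 1 for palbociclib, 4 for the breast lines and 4 for the stomach lines.

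For comparisons of 3 libraries with 3 the 10 splits are too few for a share under 0.05. Trametinib in SW48 gave 4331 genes in set 1 (highest other split 0) and 7574 in set 2 (1), palbociclib gave 7497 in SW48 (0) and 4224 in SW620 (1), and afatinib gave 75 in BT-20 (2) and 5457 in BT-474 (1). Trametinib against palbociclib gave 5465 in SW48 (1) and 4464 in SW620 (0). In SW620 with trametinib (0 and 1 as the highest other in set 1 and set 2), NCI-N87 (1) and MKN-45 (1) edgeR called 0 genes, so all 10 splits were as large. At an unadjusted p under 0.05 the counts were 366, 2492, 1523 and 664, and DESeq2 called 14, 501, 33 and 0. The 366 lie below and the 664 near the share of 0.05 of tested genes that unchanged genes give on average.

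Reads not aligned, which no comparison uses, made up a mean of 44.7% in the trametinib libraries of SW48 in set 1 (42.4 to 47.5%) against 29.0% in its controls (22.4 to 38.0%), and the difference was not tested.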

How the results depend on the processing

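The robust estimate of the dispersion and the left-out libraries of the shared calls were chosen after the data had been seen; the other alternatives were planned. Where a count moved, the cause was not tested.

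With DESeq2 size factors 258 of 259 named gene results, and all 180 list calls, held their direction and side of the threshold. Of the gene results 247 of 252 did so with DESeq2, 254 of 259 with the robust dispersion, and 1690 of 1806 with 1 library left out (83 calls lost, 13 gained). Of the 180 list calls 46 held with an estimated correlation and 140 with fry, 179 with the robust dispersion, and 1324 of 1398 with 1 library left out. With the replicate number as a block, 238 of 259 gene results and 179 of 180 list calls held, and the count was 5 in BT-20 and 0 for the stomach lines. The block was only an alternative, since numbers did not pair the libraries.

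With an absolute log2 fold change of at least 1, trametinib in SW48 left 1850 genes in set 1 and 1970 in set 2, palbociclib 1628 in SW48 and 835 in SW620, and afatinib 10 in BT-20 and 1286 in BT-474. Differences between lines left 1292 genes for trametinib in set 2, 985 for palbociclib and 1083 for the breast lines. Trametinib against palbociclib left 757 in SW48 and 989 in SW620. The SW48 sets then shared 759 genes and the drugs 948 in SW48.

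With all groups of a set in 1 fit, trametinib gave 2227 genes in SW48 and 2 in SW620 in set 1 and 632 in SW620 in set 2. Afatinib gave 1427 in NCI-N87, 7 in MKN-45 and 12 in BT-20, 437 for the stomach line difference and 1943 for the breast line difference. With no filter, SW620 with trametinib in set 2 gave 864, NCI-N87 197, BT-20 497 and the stomach line difference 140. DESeq2 gave 14 and 501 for trametinib in SW620 in set 1 and set 2, 33 in NCI-N87, 164 in BT-20, 1821 for the trametinib difference in set 1 and 23 for the stomach line difference.

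With 1 library left out, trametinib in SW620 in set 2 gave 0 to 1347 genes, the latter without trametinib 1, which also gave 483 genes shared with palbociclib where other libraries gave as few as 0. NCI-N87 gave 0 to 2108, the latter without control 1, MKN-45 0 to 1 (1 without control 1 or control 2) and BT-20 6 (without control 3) to 96. The trametinib difference in set 1 gave 493 to 2439, the latter without SW620 control 3, and the stomach line difference 0 to 1315, the latter without NCI-N87 control 1.

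Signs changed only for genes that did not pass the test. SPRY4 with trametinib was 0.14 in SW48 and −0.32 in SW620 of set 1 with the block, and with 1 library left out −0.67 to 0.90 in SW48, −1.05 to 0.38 in SW620 of set 1 and −0.0195 to 0.13 in set 2. CCND1 in SW620 of set 1 was −0.34 to 0.0547, ETV5 in SW620 of set 2 −0.0935 to 0.14, and CCNE2 and E2F1 with palbociclib in SW620 −0.10 to 0.19 and −0.31 to 0.00289. With afatinib in NCI-N87, DUSP6 was −0.0352 with the block and −0.18 to 0.32 with 1 library left out, and ERBB2 −0.16 to 0.0624. In MKN-45 ERBB2 was −0.00844 to 0.20, and ERBB3 −0.000394 with DESeq2 size factors, −0.000707 with DESeq2 and −0.0417 to 0.0614 with 1 library left out. In BT-20 ERBB2 was −0.13 to 0.0125.

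Of simulated 4-fold changes 76% were recovered for trametinib in SW620 of set 1, and 46% for the difference between lines in that set, against 2% of 2-fold changes for that difference. Of simulated 2-fold changes 9% were recovered for trametinib in SW620 of set 1 (biological coefficient of variation 0.386, 9075118 to 10622670 counts per library) and 60% in SW48 of that set (0.211, 4063382 to 8068003), so recovery went with spread and not with depth there; no simulation separated them.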

Other observations

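The values given here were chosen after the data had been seen. SW48 controls differed between the sets in NOTUM, an enzyme that inactivates WNT ligands, which stood at 0.197 ± 0.0799 CPM in set 1 and 228 ± 7.97 CPM in set 2, and in AXIN2, at 82.0 ± 40.5 and 430 ± 17.7 CPM. The sets were not tested against each other. In the table of set 1, the 5 lines of reads given to no gene summed to a mean of 58.9% of all reads in SW48 controls, 71.4% in SW48 with trametinib, 43.9% in SW620 controls and 41.8% in SW620 with trametinib.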
